A study of Homo sapiens with 12 samples.

How the data were processed

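Raw gene counts of 12 libraries, 3 in each of 4 groups, were analysed. The labels give a 2 by 2 design of siRNA (PXN or non-specific) and treatment (DHT or ethanol vehicle) in LNCaP cells, and each sample was placed by its own label. RNA was extracted with RNeasy Plus Mini kits and libraries were made with TruSeq Stranded mRNA kits, per the labels' protocols. The deposited values are whole-number counts per gene symbol that the authors made with featureCounts, per the submitters' processing notes. Those notes name Trimmomatic 0.32, STAR 2.4.2a and Subread 1.5.0p3 and the GRCh38 build. The strand setting, the gene annotation, the treatment of multiply mapped reads and the number and sequence of the PXN siRNAs are not given in the sources used here. How reads of overlapping, antisense or paralogous genes were assigned is therefore open, and values for such genes are less certain.

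The table holds 36137 gene symbols, none of them blank. Library totals were 34321000 to 38633456 counts, and 1 CPM stands for 33.65 to 38.2 counts. No pair of replicates agreed within sampling noise: the chi-square per gene lay between 6.71 and 29.8 over the 12 pairs within groups. Every one of the 12 libraries was kept.

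Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr over the 4 groups (18468 kept, 17669 left out), libraries were scaled by TMM, and 1 quasi-likelihood model with 4 group means was fitted to all 12 libraries (8 residual degrees of freedom). CPM use the TMM-scaled library size, and are given as mean ± SD of 3 libraries. Log2 fold changes are shrunken only by edgeR's default prior count. The standard error (SE) of a fold change is its size divided by the square root of the test's F value. It is derived from the test and is not an estimate by the fit itself. The contrasts tested were PXN siRNA under vehicle, PXN siRNA under DHT, DHT with non-specific siRNA, DHT with PXN siRNA, and their interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05.

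The design, the alternatives, the 16 gene lists and the rule for naming genes were set before the data were examined. The rule takes PXN, then in each pairwise contrast the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, and up to 3 members of each list with the smallest p. For the interaction it takes the 3 smallest p where no gene passes. The lists cover androgen-induced and androgen-repressed genes, DNA replication and G1/S, mitosis and G2/M, focal adhesion, MAPK and immediate early genes, sterol and fatty acid synthesis, the interferon response, unfolded protein and integrated stress response, p53 targets, hypoxia and glycolysis, YAP/TAZ targets, neuroendocrine markers, markers of other cell types, and mitochondrially encoded genes, and 1 further list that counts in the totals but is not reported here. They hold 384 symbols, 344 of them tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over all 80 tests, 31 of which passed. With a correlation estimated for each list 1 passed, that of the androgen-induced genes for DHT with non-specific siRNA.

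The replicate numbers in the labels are shared by the groups, with no statement of what they mark. Deviations from the group means were correlated between libraries with the same number, and the numbers were taken to pair 2 groups where each of the 3 pairs had a correlation over 0.1. Over all tested genes the pairs lay at 0.121 to 0.210 for PXN siRNA under vehicle, 0.145 to 0.383 for DHT with non-specific siRNA and 0.100 to 0.307 for DHT with PXN siRNA, all over the limit. They lay at 0.0769 to 0.284 for PXN siRNA under DHT, and at -0.0256 to 0.383 for the 18 pairs of the interaction, not all over it. A second version over the 11080 genes with at least 5 CPM was tried only after the outcome of the first had been seen. It gave 0.289 to 0.458, 0.574 to 0.686, 0.304 to 0.627, 0.226 to 0.557 and 0.0808 to 0.686 in the same order, and the first version was used to decide. The lowest value for DHT with PXN siRNA was 0.10039, just over the limit.

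Alternatives were other scalings (DESeq2 size factors, upper quartile), other low-count filters (none, or a mean of 1 CPM), other tests (DESeq2's Wald test, limma-voom), fits of only the groups compared, the replicate block, an adjusted p of 0.01, a test against a fold change of 1.5, and leaving out each library. Cyclic loess scaling, an offset for GC content and length with and without the replicate block, and a fit without mitochondrially encoded genes were added after seeing the data. The shared-control value came from 20 simulations of libraries with no effect. The GC and length values and gene positions came from GENCODE 29 on GRCh38, which may differ from the authors' annotation. Of the tested genes 83.5% had a GC and length value. Word searches in 3' UTRs and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

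The gene test was tested on simulated counts with known changes drawn from the real means and library sizes, the list test likewise for PXN siRNA under vehicle, and the word search on planted words and shuffled data. Of genes changed 1.5-fold, 2-fold and 4-fold, the test recovered 47.8%, 72.1% and 90.3% for PXN siRNA under vehicle, 55.4%, 60.7% and 92.3% for PXN siRNA under DHT, and 59.5%, 74.6% and 94.9% for DHT with non-specific siRNA. It recovered 56.1%, 73.5% and 89.4% for DHT with PXN siRNA, and 28.1%, 55.2% and 84.1% for the interaction. In the order of these comparisons, 6%, 5.48%, 3.85%, 3.31% and 7.38% of its calls were false. Each simulation changed 59 to 74 genes per fold in 1 group, and its libraries were drawn independently. The real PXN siRNA comparisons called 50.2% and 51.8% of genes, and libraries with the same number correlated. These shares therefore describe the simulated setting and are not error rates of the real calls. The list test found the 1 shifted list and called 0 of the other lists simulated, and the word search ranked the planted word first in 5 of 5 runs with 0 words past its limit in shuffled data.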

Results

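Poly(A) RNA was sequenced from LNCaP cells, an established androgen-sensitive prostate cancer line derived from a lymph node metastasis. The cells had been transfected for 48 h with an siRNA against PXN, which encodes the focal adhesion adaptor protein paxillin, or with a non-specific siRNA. After 12 h of serum starvation they received 2.5 nM dihydrotestosterone (DHT), a potent natural androgen, or its ethanol vehicle for 24 h. Each of the 4 groups held 3 libraries. The libraries held between 34321000 and 38633456 counts assigned to genes, and 18468 of the 36137 listed genes had enough counts to be tested. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

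PXN was read first in every library, as a check of the siRNA labels. PXN lies on chromosome 12 at 120210439 to 120265771 on the minus strand (GRCh38). Under vehicle, PXN in CPM (counts scaled to library size) was 112, 106 and 108 with non-specific siRNA (replicates 1 to 3) and 15.2, 21.2 and 14.9 with PXN siRNA. Under DHT the values were 113, 99.7 and 104 CPM against 19.96, 18.1 and 16.6 CPM. PXN mRNA was therefore 6.34-fold lower under vehicle (log2 fold change -2.66 ± 0.11, SE) and 5.805-fold lower under DHT (-2.54 ± 0.11, SE), with no overlap between groups (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p = 7.73e-09 and 9.52e-09).

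**Figure D1:**
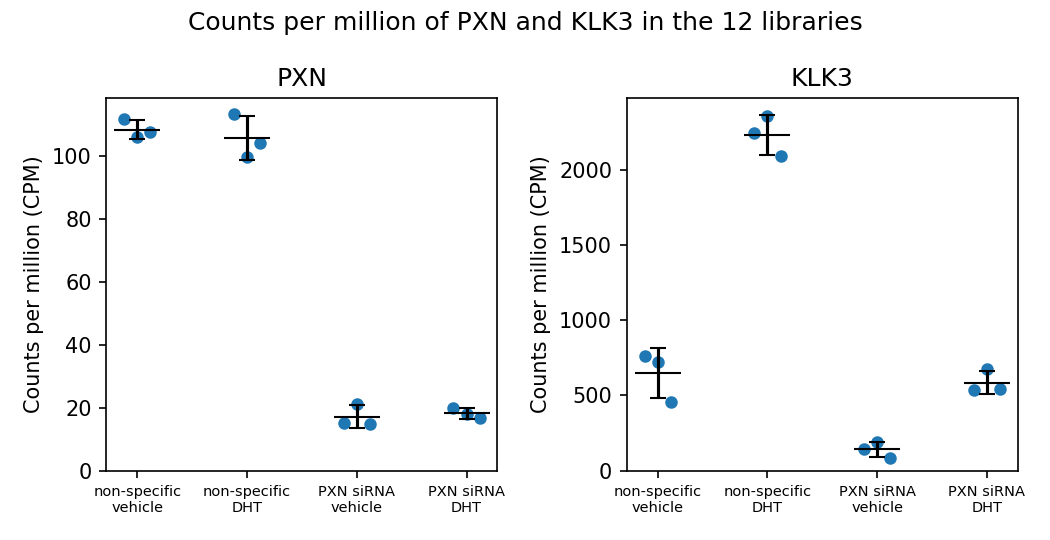
CPM of PXN and KLK3 (vertical axes, linear and starting at 0) in the 12 libraries, by group on the horizontal axis. Points are libraries, horizontal bars are group means and error bars are 1 SD (n = 3); the PXN siRNA libraries lay below the non-specific siRNA libraries for PXN under both treatments.

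The first comparison asks which transcripts differ when paxillin is depleted without added androgen. Cell cycle genes were lower throughout: all 32 tested genes of DNA replication and the G1/S transition and all 30 of mitosis and G2/M fell with PXN siRNA, with median log2 fold changes of -1.75 and -2.13. Interferon response genes were higher, with 26 of 30 past the threshold upward and a median of 1.85. Of 27 genes of sterol and fatty acid synthesis, 26 fell (median -0.70).

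Among replication genes, TK1, which encodes thymidine kinase of the salvage pathway, fell from 105 ± 2.06 to 28.0 ± 5.21 CPM (mean ± SD, n = 3). RRM1, the large subunit of ribonucleotide reductase, fell from 139 ± 2.59 to 64.2 ± 6.47 CPM. TYMS, thymidylate synthase, fell from 42.5 ± 2.91 to 12.0 ± 2.34 CPM. Among mitotic genes, BUB1B of the spindle checkpoint fell from 60.5 ± 3.995 to 13.2 ± 3.71 CPM, and CCNB1, encoding cyclin B1, fell from 137 ± 5.92 to 41.7 ± 9.70 CPM. The set test of each list against all other genes (camera, preset correlation) gave Benjamini-Hochberg adjusted p = 8.01e-43 for the replication list and 2.25e-42 for the mitosis list. Both had adjusted p = 0.196 with an estimated correlation. Adjusted over the list alone, 32 and 30 members were lower.

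Of the interferon list, IFI6 rose from 11.7 ± 1.02 to 63.9 ± 8.58 CPM, and RSAD2, which encodes the antiviral protein viperin, rose from 1.05 ± 0.259 to 18.8 ± 5.09 CPM. SAMD9 rose from 4.17 ± 0.792 to 16.1 ± 2.01 CPM. The list passed camera at adjusted p = 4.19e-16, with adjusted p = 0.219 with an estimated correlation, and 27 members were higher and 2 lower when adjusted over the list alone. The OAS and IFIT families hold similar genes that can share reads, so single members are less certain than the list. Of 8 markers of other cell types, COL1A1 and TAGLN rose as well, by 0.57 ± 0.08 and 0.56 ± 0.20 on the log2 scale, while COL3A1 fell by 0.80 ± 0.19 and LUM fell by 2.22 ± 0.46. TAGLN missed the threshold without vehicle replicate 1 or 3 of the non-specific siRNA (0.41 and 0.43) and without vehicle replicate 1 or 2 of the PXN siRNA (0.56 and 0.46).

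In lipid synthesis, ELOVL6, a fatty acid elongase, fell from 177 ± 8.28 to 39.0 ± 9.42 CPM. SCD, the stearoyl-CoA desaturase, fell from 3044 ± 110 to 1130 ± 216 CPM, and INSIG1, a regulator of sterol sensing, fell from 383 ± 17.6 to 165 ± 29.6 CPM. The list gave camera adjusted p = 1.19e-09, with adjusted p = 0.511 with an estimated correlation. Adjusted over the list alone, 26 members were lower and 1 higher.

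The androgen-induced list, fixed from general knowledge, went both ways under vehicle: 9 of 40 members rose, 19 fell and 12 did not pass, with the same 9 and 19 adjusted over the list alone, and the list as a whole did not pass camera (adjusted p = 0.309). KLK3, which encodes prostate-specific antigen, fell from 649 ± 165 to 140 ± 53.1 CPM, and PPAP2A (now PLPP1) fell from 182 ± 19.5 to 66.9 ± 13.9 CPM. ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid, rose from 23.7 ± 3.39 to 47.6 ± 4.04 CPM. Of the androgen-repressed list, 7 of 16 rose, 5 fell, and camera gave adjusted p = 0.846.

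The largest rises past the threshold, by the rule fixed for naming genes, were led by MRGPRE, an orphan G protein-coupled receptor gene, from 0.594 ± 0.0762 to 17.0 ± 7.54 CPM (log2 fold change 4.83 ± 0.44, SE). KRT75, a type II keratin gene, rose by 4.24 ± 0.28 and TRIM22, an interferon-inducible gene, by 4.07 ± 0.36 on the log2 scale. NOS3, encoding endothelial nitric oxide synthase, rose from 25.8 ± 7.48 to 297 ± 100 CPM (chromosome 7, 150990995 to 151014588). MCPH1-AS1 and DIO3OS also rose, by 3.68 ± 0.19 and 3.49 ± 0.27, but as the strand setting of the counting is not given in the sources used here, reads of antisense or overlapping genes may be mixed. After PXN, the largest falls were those of SHCBP1 (-2.66 ± 0.18), CEP55, a cytokinesis gene (-2.52 ± 0.16), MCM10, a replication gene (-2.49 ± 0.20), and TTK, a spindle checkpoint kinase gene (-2.46 ± 0.19).

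Focal adhesion genes went both ways, 9 higher and 9 lower of 38 (camera adjusted p = 0.911): LIMS1 fell by 1.09 ± 0.08 and CRKL fell by 0.78 ± 0.07 on the log2 scale. Of 20 hypoxia and glycolysis genes, 5 rose and 11 fell (camera adjusted p = 0.0137, adjusted p = 0.669 with an estimated correlation), PFKFB3 from 19.7 ± 1.99 to 6.76 ± 0.888 CPM. Of 13 YAP/TAZ targets, 7 rose and 2 fell (camera adjusted p = 0.0415, adjusted p = 0.288 with an estimated correlation). In the MAPK and immediate early list, 8 of 20 rose and 6 fell (camera adjusted p = 0.911), with CCND1, encoding cyclin D1, at 313 ± 12.6 against 140 ± 8.35 CPM. Stress response genes (6 higher, 12 lower of 22, camera adjusted p = 0.735) did not pass as a list. Lists of p53 targets (14 higher, 3 lower of 23) and neuroendocrine markers (4 higher, 1 lower of 7) passed camera only with the replicate number as a block. Their camera adjusted p was 0.0938 and 0.111 without the block, and 0.0155 and 0.0496 with it (with an estimated correlation and no block, adjusted p = 0.861 and adjusted p = 0.388). Markers of basal, stromal, endothelial and leukocyte cells did not pass (2 higher, 2 lower of 8, camera adjusted p = 0.817), and their median (0.19) and mean (-0.21) differed in sign.

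In all, 9276 genes passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 4423 higher and 4853 lower, and 2162 of them changed at least 2-fold (1440 higher, 722 lower). Testing against a fold change of 1.5 left 1957 genes. The balance of directions depends on the scaling, since upper-quartile scaling put 60.2% of calls higher, against 47.7%, and moved the median of all genes to 0.117. Mitochondrially encoded transcripts took 8.42% ± 0.305 of counts in the PXN siRNA libraries and 5.75% ± 1.10 in the others (SD, n = 6 each, two-sided exact permutation p = 0.00216, the smallest that 6 against 6 can give). That permutation takes the libraries as independent and ignores treatment and replicate number, so it may overstate the evidence. Of the 13 mitochondrial genes tested, 3 were past the threshold upward, 0 when adjusted over the list alone (camera adjusted p = 0.0896, or 0.0332 with the replicate block, and adjusted p = 0.861 with an estimated correlation and no block). Median log2 fold changes also followed the level of a gene, from 0.32 for genes under 1 CPM to -0.15 for genes over 100 CPM.

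The second comparison asks the same under DHT. The groups that moved under vehicle moved the same way: all 32 replication genes (median -1.61) and all 30 mitosis genes (median -1.94) fell, 23 of 30 interferon genes rose and 2 fell (median 1.80), and 26 of 27 lipid synthesis genes fell (median -0.79). In addition, 26 of 40 androgen-induced genes fell and 4 rose (median -1.08). KLK3 stood at 2235 ± 131 CPM with non-specific siRNA and at 584 ± 77.3 CPM with PXN siRNA under DHT (n = 3).

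Among androgen-induced genes with the smallest p, HERC3 fell from 305 ± 45.4 to 110 ± 11.8 CPM, PPAP2A from 298 ± 3.73 to 101 ± 17.1 CPM, and GNMT, glycine N-methyltransferase, from 23.7 ± 3.50 to 11.7 ± 1.30 CPM. The list passed camera at adjusted p = 2.27e-05, with adjusted p = 0.574 with an estimated correlation, and 28 members were lower adjusted over the list alone. Camera adjusted p was 5.20e-40 for replication (adjusted p = 0.196 with an estimated correlation), 5.45e-34 for mitosis (adjusted p = 0.219 with an estimated correlation), 4.75e-13 for interferon (adjusted p = 0.288 with an estimated correlation) and 6.36e-13 for lipid synthesis (adjusted p = 0.386 with an estimated correlation). Hypoxia genes fell as a list (12 lower, 4 higher, camera adjusted p = 0.00244, adjusted p = 0.603 with an estimated correlation). YAP/TAZ targets rose (8 higher, 1 lower, 0.0157, adjusted p = 0.219 with an estimated correlation), as did p53 targets (14 higher, 2 lower, 0.0169, adjusted p = 0.798 with an estimated correlation), including BBC3, a proapoptotic gene, from 11.5 ± 0.729 to 26.9 ± 4.18 CPM. Of 8 markers of other cell types 2 rose, COL1A1 by 0.82 ± 0.09 and TAGLN by 0.67 ± 0.20 on the log2 scale, and 4 fell, with COL3A1 at -0.83 ± 0.20 (list camera adjusted p = 0.817). TAGLN missed the threshold without DHT replicate 3 of the non-specific siRNA (0.57, adjusted p = 0.0524), and the other 3 that fell each missed it without at least 1 single library.

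MRGPRE again led the rises, from 0.297 ± 0.114 to 19.1 ± 8.57 CPM (63.8-fold), with log2 fold changes for KRT75 at 4.95 ± 0.30, NOS3 at 3.70 ± 0.27 and MAN1A1, encoding a Golgi mannosidase, at 3.37 ± 0.36. The falls were led by TMEM47 (-2.61 ± 0.11), PXN, DTL, a replication-coupled ubiquitin ligase gene (-2.40 ± 0.18), and SHCBP1 (-2.34 ± 0.18). In all, 9561 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 4622 higher and 4939 lower, of which 2377 changed at least 2-fold. Testing against a fold change of 1.5 left 2234 genes, and upper-quartile scaling put 60.7% of calls higher, against 48.3%, with the median of all genes at 0.130.

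The effects of PXN siRNA under vehicle and under DHT were then set side by side, since they share no library. Of the genes called in each, 3609 were higher in both and 4260 lower in both, against 1107 and 1298 for independent lists of those sizes among 18468 genes. Calls in opposite directions numbered 6 for higher under vehicle and lower under DHT, and 0 for the reverse, against 1183 and 1215 for independent lists. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.890 and Spearman rho = 0.881.

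**Figure D2:**
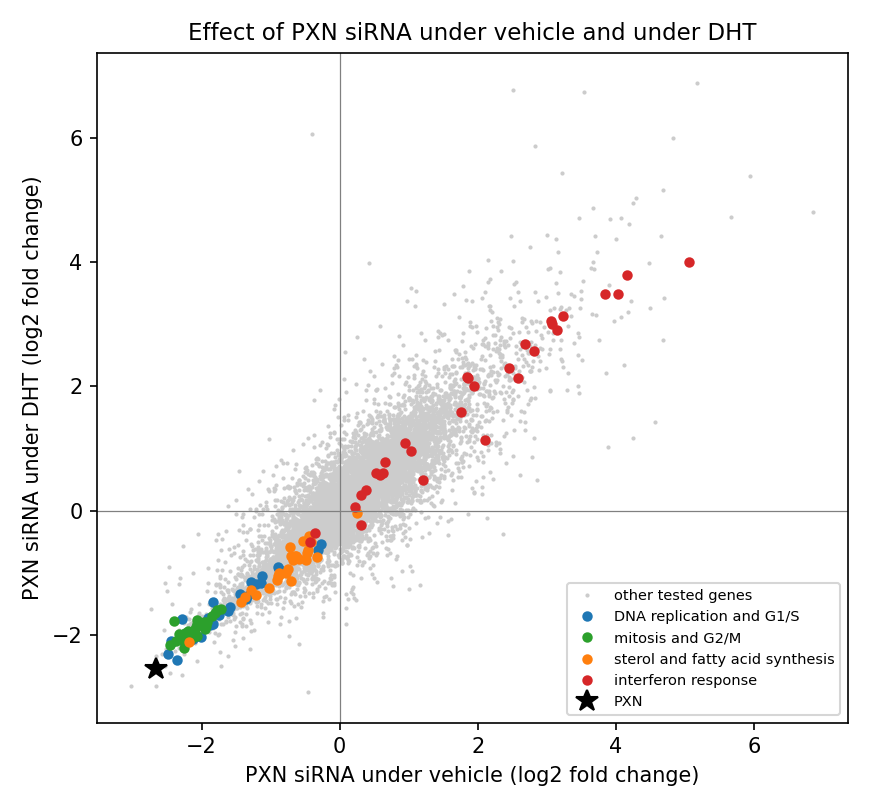
Log2 fold change of PXN siRNA against non-specific siRNA under vehicle (horizontal axis) and under DHT (vertical axis) for the 18468 tested genes, with 4 fixed gene lists in colour and PXN as a star. Replication and mitosis genes lie at the lower left (medians -1.75 and -2.13 under vehicle) and most interferon genes at the upper right (median 1.85).

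The third comparison gives the response to androgen with non-specific siRNA. DHT raised 31 of the 40 androgen-induced genes and lowered none, with a median log2 fold change of 1.10. Among them, KLK2, which encodes a kallikrein next to KLK3, rose from 52.3 ± 14.4 to 362 ± 87.7 CPM (n = 3). TRPM8, a cold-sensing ion channel gene, rose from 9.31 ± 3.68 to 59.8 ± 2.98 CPM.

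The androgen-induced list gave camera adjusted p = 1.64e-78 and kept its call at adjusted p = 0.0326 with an estimated correlation; adjusted over the list alone, 34 members were higher. The members with the smallest p were HERC3 (108 ± 12.0 to 305 ± 45.4 CPM), ALDH1A3 (23.7 ± 3.39 to 55.8 ± 4.75 CPM) and HOMER2 (76.5 ± 3.62 to 165 ± 26.1 CPM). Of the androgen-repressed list, 5 of 16 fell and 1 rose (camera adjusted p = 7.89e-05, adjusted p = 0.350 with an estimated correlation). OPRK1, an opioid receptor gene, fell from 30.9 ± 5.60 to 13.6 ± 1.87 CPM, and UGT2B28, a glucuronidation enzyme gene with close paralogs, rose from 3.01 ± 0.606 to 6.69 ± 1.15 CPM. Adjusted over the list alone, 8 were lower and 1 higher.

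Of the 27 lipid synthesis genes 4 rose, 14 when adjusted over the list alone with 1 lower (camera adjusted p = 3.83e-09, adjusted p = 0.512 with an estimated correlation). No replication gene passed alone, while the list shifted upward by a median of 0.22 (camera adjusted p = 1.14e-06, adjusted p = 0.650 with an estimated correlation). Without single libraries MCM4 (0.34 without DHT replicate 1 of the non-specific siRNA, 0.30 without vehicle replicate 2 of the PXN siRNA), MCM5 (0.34 without vehicle replicate 2 or DHT replicate 2 of the PXN siRNA) and CDT1 (0.32 without DHT replicate 3 of the PXN siRNA) passed. With the replicate block all 3 of them passed (0.30, 0.34 and 0.32). SESN1 and TP53INP1, both p53 targets, fell by 0.59 ± 0.10 and fell by 0.42 ± 0.08 on the log2 scale (list camera adjusted p = 0.00154, adjusted p = 0.686 with an estimated correlation), and AJUBA, a YAP/TAZ target, fell by 0.46 ± 0.07 (list 0.0201, adjusted p = 0.219 with an estimated correlation). HK2, hexokinase 2 of the hypoxia and glycolysis list, rose from 45.3 ± 1.28 to 66.4 ± 2.18 CPM (list 0.0415, adjusted p = 0.715 with an estimated correlation). The stress response list gave camera adjusted p = 0.0714, or 0.0145 with the replicate block (adjusted p = 0.574 with an estimated correlation and no block). TNS3, a tensin gene of the focal adhesion list, rose from 0.565 ± 0.0529 to 3.13 ± 0.457 CPM, while that list did not pass (camera adjusted p = 0.846).

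The largest rises were those of CHRNA2, a nicotinic receptor subunit gene (log2 fold change 5.72 ± 0.62, SE), HPGD, which encodes a prostaglandin dehydrogenase (3.76 ± 0.39), the coagulation factor gene F5 (3.15 ± 0.42) and the sialyltransferase gene ST6GALNAC1 (3.06 ± 0.28). The largest falls were those of PLD1, encoding phospholipase D1 (-1.84 ± 0.36), LRRC31 (-1.76 ± 0.24) and VWA2 (-1.47 ± 0.20). PLD1 missed the threshold without the DHT replicate 2 of the non-specific siRNA (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0536, range over its alternatives 7.03e-07 to 0.0536). In all, 900 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 502 higher and 398 lower, and 199 of them changed at least 2-fold (146 higher, 53 lower). With the replicate number as a block, 2236 genes passed (1140 higher, 1096 lower), among them all 900. The count was 424, 425, 521 and 504 without DHT replicate 2, DHT replicate 3, vehicle replicate 1 and vehicle replicate 3 of the non-specific siRNA, and 1362 without its DHT replicate 1.

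The fourth comparison gives the response to androgen after PXN siRNA. Of the 40 androgen-induced genes 10 rose and none fell, with a median of 0.50. KLK3 rose from 140 ± 53.1 to 584 ± 77.3 CPM (log2 fold change 2.06 ± 0.23, SE), KLK2 from 13.1 ± 7.42 to 112 ± 41.2 CPM (3.09 ± 0.37) and TRPM8 from 3.21 ± 1.12 to 17.9 ± 2.88 CPM (2.49 ± 0.26; n = 3 throughout). Each stayed below its level under DHT with non-specific siRNA in these means. KLK2 and KLK3 are close paralogs that can share reads.

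Adjusted over the list alone, 26 androgen-induced genes were higher (camera adjusted p = 2.16e-55, adjusted p = 0.0501 with an estimated correlation). GRIN3A, a glutamate receptor subunit gene, rose from 4.08 ± 1.10 to 19.1 ± 6.04 CPM and ELOVL7, a fatty acid elongase gene, from 11.3 ± 2.95 to 32.3 ± 3.38 CPM. The replication list moved upward with no single member past the threshold, or 7 adjusted over the list alone (median 0.35, camera adjusted p = 8.40e-17, adjusted p = 0.357 with an estimated correlation). Without vehicle replicate 2 of the PXN siRNA, EXO1, CDC6 and the mitotic gene CDC20 passed (0.92, 0.92 and 0.76), and without its DHT replicate 3 CDT1 did (0.57). With the replicate block EXO1, CDC6 and CDT1 passed (0.69, 0.62 and 0.43). Mitosis (0.19, camera adjusted p = 3.54e-07, adjusted p = 0.659 with an estimated correlation) and lipid synthesis (0.17, camera adjusted p = 3.54e-05, adjusted p = 0.659 with an estimated correlation) shifted likewise, and the androgen-repressed list shifted downward (-0.16, camera adjusted p = 0.00445, adjusted p = 0.512 with an estimated correlation). The interferon, p53 and YAP/TAZ lists gave camera adjusted p = 0.0529, 0.0824 and 0.0612, and 0.0286, 0.0162 and 0.0171 with the replicate block. With an estimated correlation and no block they gave adjusted p = 0.798, adjusted p = 0.861 and adjusted p = 0.288.

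In all, 34 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), all higher, 21 of them at least 2-fold, and 1378 genes had an unadjusted p under 0.05. No gene was lower, against 13 by DESeq2 and 0 by limma-voom. CHRNA2 rose by 4.18 ± 0.62 on the log2 scale. Its call was lost without vehicle replicate 1, vehicle replicate 3 or DHT replicate 2 of the PXN siRNA (log2 fold changes 4.32, 3.76 and 3.96), and with limma-voom (adjusted p = 0.289), also after cyclic loess scaling (adjusted p = 0.257). ST6GALNAC1, at 2.10 ± 0.28, lost its call without vehicle replicate 3 (1.89). With the replicate number as a block, 346 genes passed (249 higher, 97 lower), including all 34. The count was 8, 15, 11 and 16 without vehicle replicate 3, vehicle replicate 1, DHT replicate 2 and DHT replicate 3 of the PXN siRNA, and 22 without DHT replicate 3 of the non-specific siRNA. It was 68 and 70 without vehicle replicate 2 and DHT replicate 1 of the PXN siRNA, and 71 without DHT replicate 1 of the non-specific siRNA.

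**Figure D3:**
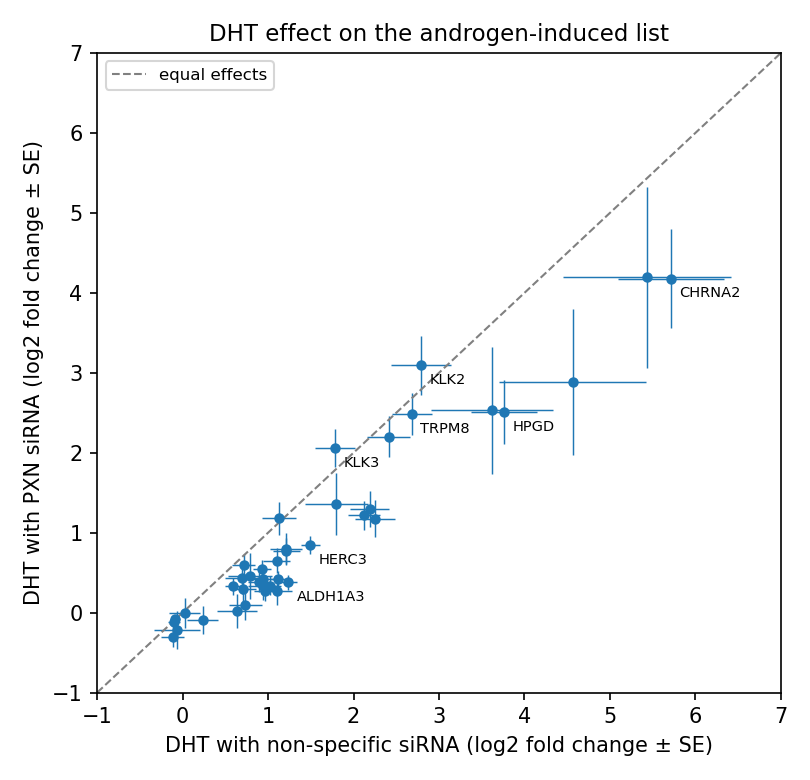
Log2 fold change of DHT against vehicle with non-specific siRNA (horizontal axis) and with PXN siRNA (vertical axis) for the 40 androgen-induced genes, with standard errors as bars and a dashed line of equal effects. Most points lie below the line, with medians of 1.10 and 0.50, while KLK2 and KLK3 lie above it.

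The difference between the DHT responses was tested directly as an interaction. FAM174B, ALDH1A3 and TMEM164 had the smallest p, and none passed in the edgeR test with the 4 group means. FAM174B stood at 42.2 ± 3.57 and 94.7 ± 9.43 CPM with non-specific siRNA and at 54.4 ± 2.15 and 69.9 ± 4.99 CPM with PXN siRNA (vehicle, then DHT, n = 3). Its interaction was -0.81 ± 0.12 (log2, SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.115, range over its alternatives 8.53e-07 to 0.543). ALDH1A3, at -0.86 ± 0.14, and TMEM164, at -0.69 ± 0.11, each had adjusted p = 0.156 in the same test. The number of genes past the threshold was 0 in edgeR with the 4 group means, 0 in limma-voom and 37 in DESeq2. With the replicate block in edgeR it was 58, among them FAM174B, ALDH1A3 and TMEM164. The replicate numbers did not meet the pairing limit for the interaction, however. In edgeR without the block, 778 genes had an unadjusted p under 0.05. Without DHT replicate 1 of the non-specific siRNA 43 genes passed, among them FAM174B, ALDH1A3 and TMEM164 (-0.89, -0.92 and -0.75). Without its vehicle replicate 1 or 2, 1 gene passed in each case, ALDH1A3 (-0.98) and FAM174B (-0.88).

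As lists, the androgen-induced genes had a DHT effect lower by a median of 0.45 on the log2 scale with PXN siRNA, a difference of -0.45 (camera adjusted p = 1.56e-23, adjusted p = 0.196 with an estimated correlation), and 8 members passed adjusted over the list alone. Over that list, the slope of the DHT effect with PXN siRNA on that with non-specific siRNA was 0.786 ± 0.217 (jackknife SE over single libraries, without regard to their groups). The line had an intercept, so an equal loss of effect in every gene would not lower this slope. The slope was 0.553 over the genes called with non-specific siRNA and 0.767 over those called with PXN siRNA, and a slope over genes chosen in one arm leans towards that arm. All 34 genes called with PXN siRNA were among the 502 rises with non-specific siRNA, against 0.924 for independent lists. In the other arm, 483 of the 502 rises and 389 of the 398 falls had the same sign, with medians of 0.26 and -0.20 against 0.58 and -0.48. Those medians are of genes chosen in 1 arm, which favours that arm. Across genes, which are not independent replicates, the DHT effects had Pearson r = 0.487 and Spearman rho = 0.409.

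Genes that responded to DHT were also compared with those that differed with PXN siRNA. Of the 502 genes raised by DHT with non-specific siRNA, 312 were lower with PXN siRNA under DHT, against 134 for independent lists, and 28 were higher, against 126. Of the 398 lowered, 225 were higher, against 99.6, and 41 were lower, against 106. These comparisons share the DHT libraries of the non-specific siRNA. Simulated libraries with no effect gave a correlation of -0.503 (observed -0.358) and a covariance of -0.0299 (observed -0.105, difference -0.0751). They gave a mean of 0 shared calls, but without any effect almost no gene is called in either comparison. That count was therefore set in advance and does not measure how many observed shared calls come from the shared libraries. With PXN siRNA under vehicle, which shares the vehicle libraries, 166 rises were lower (132 for independent lists), 114 were higher (120), 129 falls were higher (95.3) and 107 were lower (105). There the simulated correlation was 0.499 (observed -0.0210) and the simulated covariance 0.0293 (observed -0.00597, difference -0.0353). The simulated shared calls, 0.05, have the same limit. The control libraries were not split between the comparisons. Under DHT, where sharing alone gave a negative correlation, part of the excess in opposite directions may therefore come from the shared libraries. Under vehicle, sharing alone gave a positive correlation of 0.499. That argues against sharing as the reason for the excess in opposite directions there. The shared calls in all directions numbered 606 and 516, and 1690 and 1544 with the replicate block. Without DHT replicate 1 of the non-specific siRNA they numbered 960 and 809, without its DHT replicate 2 276 and 241, and without its DHT replicate 3 276 and 246. Without its vehicle replicates 1 and 3 the 606 became 364 and 363, and the 516 became 285 and 266.

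In some lists the median, the mean and the direction of the camera test did not share a sign, and none of these lists passed without the replicate block. With PXN siRNA under DHT these were markers of other cell types (median -0.27, mean -0.34, camera upward) and focal adhesion (0.04, 0.02, downward). For DHT with non-specific siRNA they were the MAPK list (-0.07, -0.05, upward), other cell types (-0.06, 0.14, upward), focal adhesion (-0.01, 0.07, upward), neuroendocrine markers (0.09, -0.31, downward) and mitosis (-0.01, 0.01, upward). For DHT with PXN siRNA it was focal adhesion (-0.02, 0.04, downward). For the interaction they were the stress response (0.00061, -0.043, downward), focal adhesion (0.00081, -0.034, downward) and other cell types (0.06, -0.12, upward).

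**Figure D4:**
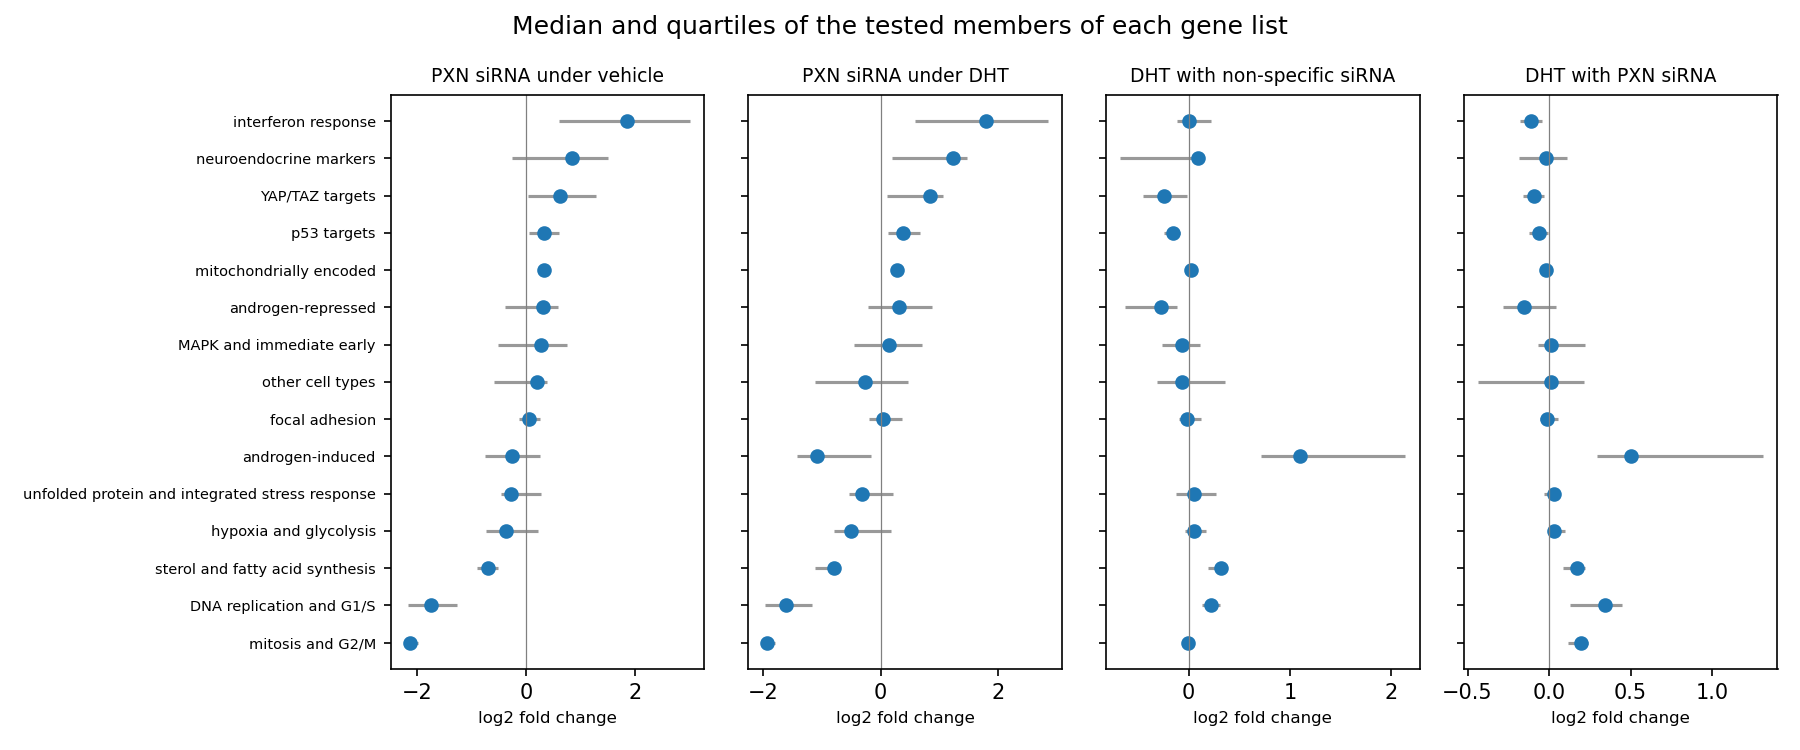
Median log2 fold change (points) and quartiles (bars) of the tested members of each reported gene list in the 4 pairwise comparisons, each panel with its own horizontal scale. The androgen-induced list has medians of -0.26, -1.08, 1.10 and 0.50 from left to right.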

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

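Of the tests below, those on GC content and length, on library scaling, on an innate response to siRNA, on the size of the DHT effects and on seed pairing as the reason for most falls, and the splits with the replicate block, were chosen only after the result was seen.

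The DHT response differed between the siRNA groups for 5 gene lists when the difference itself was tested with camera at the preset correlation. The androgen-induced list had a lower estimated DHT effect with PXN siRNA, with a median difference of -0.45 on the log2 scale (camera adjusted p = 1.56e-23, and adjusted p = 0.196 with an estimated correlation). The androgen-repressed list had a median difference of 0.32 (adjusted p = 0.0336; adjusted p = 0.650 with an estimated correlation), less repression in the PXN siRNA groups. Mitosis genes differed by 0.19 (adjusted p = 3.90e-05; adjusted p = 0.715 with an estimated correlation) and p53 targets by 0.11 (adjusted p = 0.0285; adjusted p = 0.798 with an estimated correlation). Lipid synthesis genes differed by -0.14 (adjusted p = 5.07e-04; adjusted p = 0.715 with an estimated correlation). No list kept its call with an estimated correlation.

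The first pattern weighed is the breadth of the response to PXN siRNA, with 9276 genes changed under vehicle. Bias by GC content or transcript length as the whole of it is argued against, since 11019 genes passed with an offset for both and the replicate block, against 10628 with the block alone. The offset moved the balance of directions, from 49.0% to 58.9% of calls higher, so which genes were called higher or lower depends in part on it. Seed pairing of the siRNA remains open for some genes. The leading word of 7 bases, CACACAT, which PXN itself holds, was in 17.1% of the genes lower in both arms. That met a bound of 10% written before the result was seen, but 14.6% of all 13302 genes searched hold the word, so that bound separates little. PXN holds 4 of the 7 words past the limit for falling genes, and 27.3% of all words tested. ACACACA and CACACAC, ranked 2 and 4, overlap CACACAT in sequence and are not in PXN. The presence of CACACAT in PXN is therefore no sign of an siRNA seed by itself. AGCCTAA and CCTGAAC, ranked 3 and 7, are also in PXN. Genes with these words had median log2 fold changes, averaged over both treatments, of -0.127 and -0.118, against -0.030 and -0.029 without them. The words were in 9.96% and 12.4% of the falling genes and 8.15% and 10.2% of all. TGCCTCA, the remaining PXN word, was in 23.8% and 23.3%. Whether any of them is the siRNA seed cannot be told without the siRNA sequence. Of the falling genes 56.2% hold none of the 4 leading PXN words, against 60.0% of all genes, which argues against seed pairing through those words as the direct reason for most falls. Loss of paxillin itself, which the design names, was not separated from other actions of the siRNA, whose number and sequence are not given in the sources used here.

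The second pattern is the rise of interferon response genes, with a median of 1.85 under vehicle. Leukocytes or other cells in the cultures are argued against, since the markers of such cells had a median of at most 0.123 CPM in the PXN siRNA libraries, and the leukocyte markers PTPRC, CD68 and LYZ had means of 0.0364, 0.0905 and 0.0365 CPM. COL1A1, TAGLN and VWF, which are among the markers, stood higher in these libraries, at 32.8, 8.35 and 18.8 CPM against 20.2, 5.44 and 15.4 CPM. The stromal genes COL1A2 and DCN stood at 0.0184 and 0.0181 CPM, and COL3A1 went from 6.11 to 3.48 CPM. The choice among the scalings tried is argued against as the reason, since the lowest median over them and both treatments was 1.66. These scalings moved the median of all genes to at most 0.130, so they were unlikely to bring the list to 0. A larger error of scaling was not tested. An innate response to the siRNA itself and an effect of paxillin loss cannot be told apart (median 1.85), because every library with PXN siRNA also had lower PXN mRNA.

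The third pattern is the smaller number of genes called for DHT after PXN siRNA, 34 against 900, or 346 against 2236 with the replicate block. A larger spread between the PXN siRNA libraries is argued against, since their residual spread was 0.966 of that of the other libraries, though leaving out single libraries moved this ratio between 0.855 and 1.08. Smaller effects of DHT remain open: the slope over the androgen-induced list was 0.786 with a jackknife SE of 0.217, and the median difference of -0.45 had a jackknife SE of 0.27. This jackknife ignores the groups and the replicate numbers of the libraries, so both SEs may misstate the spread. Without single libraries the slope lay at 0.647 to 0.872 and the median difference at -0.61 to -0.31. The slope is that of a line with an intercept, so it does not register an equal loss in every gene. No biological explanation was tested.

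The libraries were also divided in other ways. For 6 libraries in equal groups there are 10 splits, too few for a share under 0.05. Every split but the real one puts libraries of both real groups on each side. The difference between the real groups then adds to the spread, which favours few calls. Low counts in these splits therefore say little about chance. For PXN siRNA under vehicle, PXN siRNA under DHT and DHT with non-specific siRNA, 1 of 10 splits, the real one, gave as many genes (9276, 9561 and 900), and the highest other split gave 0. For DHT with PXN siRNA, 2 of 10 splits gave as many as the real 34, and the highest other gave 79, with vehicle replicate 2 and DHT replicates 1 and 2 on one side. These splits leave out the block and most of them do not part the pairs, as that split does not. For the comparisons that the replicate numbers pair, 4 splits part every pair, also too few, and all but the real one mix the groups likewise. With the block the real ones gave 10628 for PXN siRNA under vehicle, 2236 for DHT with non-specific siRNA and 346 for DHT with PXN siRNA, and the highest other gave 0 in each, as it did without the block. For the interaction, edgeR with the 4 group means called 0 genes (778 at an unadjusted p under 0.05), DESeq2 37 and limma-voom 0. Of 100 splits 100 gave as many as 0, which a count of 0 makes certain, so this comparison says nothing about chance. The highest other gave 532, and the reason was not tested. That split kept the DHT libraries of the non-specific siRNA together and mixed the PXN siRNA libraries of both treatments, so it sets a DHT effect in one arm against a mixture in the other. Other splits of this make-up gave between 0 and 380 genes, so the make-up alone does not account for the count.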

How the results depend on the processing

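Cyclic loess scaling, the offset for GC content and length with and without the replicate block, and leaving out mitochondrially encoded genes were tests chosen only after seeing the data.

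Testing against a fold change of 1.5 left 1957, 2234, 79 and 10 genes for PXN siRNA under vehicle, PXN siRNA under DHT, DHT with non-specific siRNA and DHT with PXN siRNA, as a stricter test calls fewer. An adjusted p under 0.01 left 406 and 11 for the DHT comparisons. The replicate block gave 2236 and 346 for them and 58 for the interaction, and with the GC and length offset as well 2465, 270 and 101. For DHT with PXN siRNA and the interaction, no low-count filter gave 188 and 35, and DESeq2's Wald test 143 and 37. Fitting only the groups compared gave 18 for DHT with PXN siRNA, with fewer libraries to estimate the spread, and gives no separate value for the interaction, which uses every group. DESeq2 size factors gave 1 for the interaction. Except where its own construction is named, the cause was not tested.

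Leaving out 1 library gave 7769 to 9358 and 8249 to 9831 genes for PXN siRNA under vehicle and DHT. DHT with non-specific siRNA ranged from 424 (without its DHT replicate 2) to 1362 (without its DHT replicate 1), with 425 without its DHT replicate 3, 521 without its vehicle replicate 1 and 504 without its vehicle replicate 3. DHT with PXN siRNA ranged from 8 (without its vehicle replicate 3) to 71 (without DHT replicate 1 of the non-specific siRNA). Its other values beyond 1.5 times were 15 and 68 without its vehicle replicates 1 and 2, 70, 11 and 16 without its DHT replicates 1, 2 and 3, and 22 without DHT replicate 3 of the non-specific siRNA. The interaction ranged from 0 to 43 (without DHT replicate 1 of the non-specific siRNA), with 1 without its vehicle replicate 1 or 2. PXN stayed lower, at -2.85 to -2.57 under vehicle and -2.61 to -2.47 under DHT.

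Of 80 list tests 31 passed, 1 with an estimated correlation, 21 with fry, 43 with the block and 32 with DESeq2 size factors. Calls the block added included neuroendocrine markers for PXN siRNA under DHT (0.0241) and lists for the interaction (interferon 0.0264, stress response 0.0370, whose median and mean differ in sign without the block). With an estimated correlation and no block these gave adjusted p = 0.306, adjusted p = 0.798 and adjusted p = 0.669. The correlation of the PXN siRNA effects was 0.890 in the main fit, and that of the DHT effects 0.487. Both depended strongly on the low-count filter. With no filter they fell to 0.302 and 0.0467, and with a mean of at least 1 CPM they rose to 0.951 and 0.688. Without single libraries they lay at 0.861 to 0.886 and 0.402 to 0.499. Fewer genes near the counting floor enter at 1 CPM. Shared calls rose from 606 to 1690 and from 516 to 1544 with the block, and without single libraries lay at 276 to 960 and 241 to 809.

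Of 242 single-gene results, 217 kept their side of the threshold with the block and 25 passed it newly, among them FAM174B, ALDH1A3 and TMEM164 for the interaction (-0.81, -0.85 and -0.69). The replicate numbers do not pair the samples there by the limit set, while 12 of 12 libraries correlated best with their own number, a hint from the data and not the design. 241 kept it with upper-quartile scaling, 239 with DESeq2 size factors, 236 with limma-voom and 226 with DESeq2's test. Results that changed sign had not been called. For DHT with non-specific siRNA these were, without single libraries, CENPA (-0.23 to 0.0016), ENO2 (-0.33 to 0.023), MT-ND4L (-0.081 to 0.32), MT-ND3 (-0.12 to 0.16) and MT-CYB (-0.074 to 0.30), and MT-ND3 with the GC and length offset (0.0044, and 0.0068 with the block). For DHT with PXN siRNA they were DLL3 (-0.059 to 0.46), ANXA1 (-0.92 to 0.0043), S100A2 (-0.66 to 0.033) and MT-ATP8 (-0.11 to 0.036) without single libraries, and with the offset IRF7 (-0.033, and -0.032 with the block) and MT-ATP8 (0.0017, and 0.0038 with the block). Depth limits genes near the floor: 4442 tested genes had a mean under 1 CPM.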

Other observations

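No test in this part was chosen after a result was seen, and the values below stand without explanation. The PXN siRNA libraries held 28584 ± 544 genes with at least 1 count and the non-specific siRNA libraries 26735 ± 548 (mean ± SD, n = 6 each). Vehicle replicate 2 of the non-specific siRNA had 7.55% mitochondrial counts, against 4.69% in replicate 1.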
